A study of Caenorhabditis elegans with 24 samples.

How the data were processed

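DamID libraries of muscle nuclei from C. elegans were analysed from the deposited tables of binned reads. Per the labels, larvae fed Dam-minus bacteria were grown for 26 h at 22.5 °C, 200 ng of genomic DNA was digested with DpnI for 6 h, and the fragments were amplified and sequenced. DpnI cuts only GATC sites methylated by Dam. The design text names the intestine, whereas the sample labels name body wall muscle and the recombinase driver myo-3 is a muscle gene, so the tissue is given here as the sample labels state it.

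The count values are mapped reads per 100 kb and 10 kb bin of the ce11 genome, which the authors deposited as raw counts without normalization, with the 3 replicates apart. The log2 values, also deposited by the authors, are the Dam-EMR over GFP-Dam ratio of each strain, each library scaled to its total and the 3 ratios averaged. Recomputing them from the counts gave the 100 kb values exactly to rounding. The 10 kb values needed 1 read added, and still differed by up to 0.361 in the Y59C strain, so the deposited log2 values were used at 100 kb only. The aligner and its filters are not given in the sources used here. The tables hold 1006 bins of 100 kb, of which 1005 are nuclear, and 10032 bins of 10 kb, of which 2 hold the value 1 in all 24 libraries and so carry no count. These 2 lie on V (8650001 to 8660000) and III (6720001 to 6730000), inside 100 kb bins with excess reads in some libraries. Median reads per 100 kb bin ran from 19 to 4148 in Dam-EMR libraries and from 2037 to 12942 in GFP-Dam libraries. PCR reads without molecular identifiers are not independent molecules, so floors given from counts cover counting error only, and p-values measure the spread between samples.

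The 24 libraries formed 8 groups of 3. Counts were fitted with edgeR 4.0.16 (quasi-likelihood, TMM factors, filterByExpr) in R 4.3.3, with association meaning Dam-EMR against GFP-Dam within a strain, and a difference meaning the change of that ratio between strains. Bins with a Benjamini-Hochberg adjusted p under 0.05 were called. DESeq2 1.42.0, limma 3.58.1 on the log2 ratio of each pair, and limma voom with library weights, the last chosen after seeing the data, were run beside it. Arms were the outer 33% of each chromosome at each end, and arm minus centre values were means over bins of the log2 ratio with 1 read added, compared by exact two-sided permutation or sign-flip tests. The 18 zones were tested with limma, and the version of the zone values centred on the median bin of each pair was added after seeing the data. The comparisons between strains, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The alternatives voom, reads summed over rounds, leaving out 4 bins with excess or ribosomal DNA reads, leaving out the shallowest pair and centred zone ratios were added after seeing the data. The averages over the 4 strains, over cec-4 states and over lamins were added after the data had been seen.

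Gene lists were tested in 10 kb bins, a gene being given the bin of its midpoint. The 21 lists were body wall muscle, pharyngeal muscle, intestine, hypodermis, neurons, germline, housekeeping, developmental transcription factors, heat shock, nuclear envelope and anchors, chemoreceptors, F-box, C-type lectins, nuclear hormone receptors, MATH-BATH, ribosomal proteins, cuticle collagens, cytochromes P450, UDP-glucuronosyltransferases, insulin-like genes and histones. They were tested with limma's camera at a preset correlation of 0.01 and with an estimated one, and list medians were placed among 10000 random bin sets matched on chromosome and zone. For the comparisons of Y59C with GFP::LMN-1 and of Y59C cec-4 with Y59C, named genes were up to 4 per list with the largest absolute log2 change among those called over the list alone. Where none was called, the gene with the smallest p is given. Where the libraries of a strain held 0 Dam-EMR reads in a bin, the change was computed against a floor of 3 reads over the group, and the fitted fold is not given.

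Replicate numbers are taken as rounds grown in parallel. Libraries of a fusion from the same round correlated at a median r of 0.635 (GFP-Dam) and 0.22 (Dam-EMR) over bins, against −0.375 and −0.159 for different rounds. Bins within a library are not independent replicates. All GFP-Dam libraries had fewer reads on arms than in centres, so values below 0 cannot be of the full read profiles. They must describe deviations from a shared profile, where values below 0 between rounds are partly forced. Only the contrast of same with different rounds can be read. The pairs were formed within rounds, and round as a block was an alternative. In counts simulated with the dispersion of these libraries for the Y59C to GFP::LMN-1 comparison, 20%, 86%, 96% and 100% of 50 bins with 2-, 4-, 8- and 16-fold changes were recovered, with 7 false calls. The other alternatives were RLE factors, library totals alone, no filter on counts, the 10 kb bins, only the groups compared, arms of 25%, recombination-map arm boundaries, the median over bins, a pseudocount of 10, and leaving out each round. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.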

Results

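DNA adenine methyltransferase identification (DamID) was used to map where the inner nuclear membrane protein emerin touches the genome in body wall muscle of Caenorhabditis elegans. A fusion of the bacterial methyltransferase Dam to emerin (Dam-EMR, from the gene emr-1) marks GATC sites close to the nuclear envelope, and a freely diffusing GFP-Dam fusion marks sites that are accessible anywhere in the nucleus. Per the labels, both fusions sat behind the un-induced heat shock promoter hsp-16.41 and were switched on in muscle by a recombinase under the myo-3 promoter. Each fusion was measured in 4 strains. The strains carried either a wild-type GFP-tagged lamin (GFP::LMN-1) or the same lamin with the Y59C substitution, a change of the kind that causes Emery-Dreifuss muscular dystrophy in people. Each lamin was combined with an intact cec-4 gene or with a cec-4 mutation, and CEC-4 is the chromodomain protein that anchors histone H3 lysine 9 methylated chromatin at the nuclear envelope. The strains are called the GFP::LMN-1, GFP::LMN-1 cec-4, Y59C and Y59C cec-4 strains. Every combination of fusion and strain had 3 replicate rounds, which gave 8 groups, 24 libraries and 12 pairs of a Dam-EMR library with the GFP-Dam library of the same strain and round.

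Read totals differed between the fusions. The Dam-EMR libraries of rounds 1, 2 and 3 held 903351, 547403 and 3121281 mapped reads in the GFP::LMN-1 strain. In the GFP::LMN-1 cec-4 strain they held 731953, 3108540 and 6936179. In the Y59C strain they held 645717, 2589969 and 35370, and in the Y59C cec-4 strain 210091, 4282156 and 3117031. The GFP-Dam libraries, in the same order, held 16650524, 2728755 and 8191693 reads, then 19442779, 3486206 and 8374875, then 15329232, 6002369 and 11019455, and finally 15785799, 3052978 and 5965995. The shallowest library, Dam-EMR of the Y59C strain in round 3, had a median of 19 reads per 100 kb bin. Between 0.772% and 42.2% of 10 kb bins held no read in a Dam-EMR library, against 0.211% to 1.35% in a GFP-Dam library. Counting alone would leave fewer Dam-EMR bins empty, for example 0.57% in the round 2 library of the GFP::LMN-1 cec-4 strain, where 21.2% were empty, and 0.679% in that of the Y59C strain, where 20.9% were.

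The genes carried by the constructs and mutated in the strains were examined first, each through the 10 kb bin at its midpoint (ce11 coordinates). The bin of the lamin gene lmn-1 (I, 8763041 to 8765631) held 1661.5 ± 2706.4 normalised reads (counts scaled to the library total, CPM) in the Dam-EMR libraries and 145 ± 65.4 in the GFP-Dam libraries (mean ± SD, n = 12 each). Its log2 ratio, centred on the median bin of each pair, was 2.36 ± 2.17 and above 0 in 11 of 12 pairs (exact two-sided sign-flip test, adjusted p over the 7 genes = 0.012). The round means of that ratio were 3.74, 2.53 and 0.82. The hsp-16.41 bin (V, 1805178 to 1805875), which holds the promoter sequence used in the constructs, averaged 947 ± 1472.3 against 161 ± 39 CPM, with a centred log2 ratio of 1.65 ± 1.81 that was positive in 10 of 12 pairs (exact sign-flip adjusted p = 0.012). The emr-1 bin (I, 1842445 to 1843222) averaged 567 ± 931 against 157 ± 40.2 CPM and was positive in 10 of 12 pairs (centred log2 ratio 0.94 ± 1.60, exact sign-flip adjusted p = 0.123). The myo-3 bin (V, 12226816 to 12234343), which encodes a body wall muscle myosin, averaged 407 ± 222 against 516 ± 125 CPM (centred log2 ratio −0.40 ± 1.08, positive in 5 of 12 pairs, exact sign-flip adjusted p = 0.41). For unc-119 (III, 10902641 to 10908935) the values were 35.8 ± 22 and 44.9 ± 21.6 CPM, with a ratio of −0.14 ± 0.65. For baf-1 (III, 9467464 to 9468058), which encodes the chromatin protein that binds emerin, they were 566 ± 1496 and 192 ± 82.4, with a ratio of 0.09 ± 1.75 and one Dam-EMR library at 5313.4 CPM.

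The cec-4 bin (IV, 7576181 to 7577325) did not separate cec-4 mutant from cec-4 intact libraries. In the GFP-Dam libraries its level was 7.72 ± 0.25 log2 CPM in the 6 cec-4 mutant libraries and 7.58 ± 0.20 in the other 6 (exact permutation p = 0.333). The bin is larger than the gene and than the allele's lesion, so this level checks nothing about the deletion. A 10 kb read count likewise cannot tell the Y59C codon from the wild-type one. The level of the lmn-1 bin in the GFP-Dam libraries was 6.98 ± 0.25 in the Y59C strains and 7.21 ± 0.63 in the wild-type lamin strains (n = 6 each, exact permutation p = 0.522).

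Across the 4 strains together, the ratio of Dam-EMR to GFP-Dam reads was higher on autosomal arms than in autosomal centres. Dam-EMR reads exceeded GFP-Dam reads in 69 of 1004 tested 100 kb bins and fell short in 25 (edgeR quasi-likelihood, adjusted p under 0.05). Chromosome V held 33 of the higher bins, chromosome II 15 and chromosome IV 10, while chromosomes I and III held 4 each and X held 3. The arms of the autosomes, taken as the outer 33% at each end, held 62 of the 69 higher bins, 11.4% of the 546 bins tested there, against 4 of 280 bins (1.43%) in the autosomal centres and 1.69% of 178 bins on X. The lower bins lay mostly in the centres, with 15 there (5.36%), 6 on X (3.37%) and 4 on the arms (0.733%).

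Of the 8 higher bins that were positive in all 12 pairs, the one with the largest ratio lay on the right arm of chromosome III (12900001 to 13000000), with a log2 ratio of 1.86 (SE 0.35, edgeR adjusted p = 0.00648). It contains unc-25, which encodes glutamic acid decarboxylase, the neuropeptide gene flp-14, the nuclear pore gene npp-25 and the zinc transporter gene ttm-1. Among the other named bins, the bin on the right arm of V from 17500001 to 17600000, with chemoreceptor genes such as srw-31 and srz-90 and 6 F-box genes including fbxa-136, had a ratio of 1.41 (SE 0.33, positive in 10 of 12 pairs). A bin of the same arm with 7 F-box genes of the fbxb group (19200001 to 19300000) had 1.22 (SE 0.29, 10 of 12 pairs), and the bin with clec-262, srh-177 and ins-35 (20300001 to 20400000) had 1.40 (SE 0.33, 10 of 12). On the left arm of II the bin with sri-36, sri-39, sri-74 and bath-13 (2500001 to 2600000) had 1.16 (SE 0.30, 11 of 12). On the right arm of IV the bin with aptf-2, gcl-1 and fezf-1 (13400001 to 13500000) had 1.39 (SE 0.31, 11 of 12), and the bin from 16700001 to 16800000 had 1.29 (SE 0.39, 10 of 12). The bin on the left arm of V with hsp-16.2 and hsp-16.41 (1800001 to 1900000) had 1.07 (SE 0.25, 11 of 12), and it holds the promoter sequence of the constructs. The bins of lmn-1 (I, 8700001 to 8800000, log2 1.41, SE 0.32, 9 of 12) and emr-1 (I, 1800001 to 1900000, log2 0.60, SE 0.16, 10 of 12), both also construct genes, were among the 69. The largest ratios of all, 4.35 in the X bin of drd-5 and npr-28 (8 of 12 pairs) and 3.82 in the V bin that holds asp-13 and ZC190.4 (9 of 12), went with large shares of the Dam-EMR reads of round 1, up to 4.26% and 22.7% of a library. The next largest, 3.64 (SE 0.66, edgeR adjusted p = 0.00514, 9 of 12), was on the right arm of V (18700001 to 18800000). That bin holds 7 C-type lectin genes.

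The lowest ratio that was negative in all 12 pairs was in the middle of IV (10500001 to 10600000), at −0.76 (SE 0.19, edgeR adjusted p = 0.0177). This bin contains zim-1, zim-2, zim-3 and him-8, a cluster of zinc finger genes for the meiotic pairing centres. The middle of V from 10600001 to 10700000, with the pharyngeal homeobox gene ceh-22 and the phosphatase gene gsp-1, had −0.72 (SE 0.15, positive in 2 of 12 pairs). The right arm of IV from 16100001 to 16200000, with hlh-32 and gln-3, had −0.70 (SE 0.18, 2 of 12). On X, the bin with the kinase gene sek-1 (7800001 to 7900000) had −0.50 (SE 0.13) and the bin with the collagen IV gene let-2, the acetylcholinesterase gene ace-1 and nhr-28 (16300001 to 16400000) had −0.49 (SE 0.15), and both were negative in all pairs. Higher bins held 4.1 chemoreceptor genes each, lower bins 0.08 and the other 910 bins 1.11, with 24.1, 20.2 and 19.5 protein-coding genes per bin. The averaged comparison and the rule for its named bins (largest ratios among those positive in at least 10, or at most 2, of 12 pairs) were chosen after the data were seen.

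Because neighbouring bins are not independent, the placement was tested by sliding the calls along the genome. Of 1004 circular shifts, 20 put as many of the higher bins on autosomal arms as observed (89.9% of the bins against 54.4% of all bins, permutation p = 0.0199), and 29 did so for lower bins in autosomal centres (60% against 27.9%, permutation p = 0.0289). DESeq2 called 110 higher and 47 lower bins, limma on the pair ratios 2 and 1, and edgeR with library totals as the only scaling 38 and 5. With round as a block edgeR called 65 higher and 41 lower bins, of which 57 and 24 were shared with the 69 and 25. Without round 1 the calls were 45 and 34, of which 18 higher and 14 lower bins were shared with the 69 and 25. Without round 2 they were 50 and 2, and without round 3 they were 1 and 0. In 10 kb bins 126 were higher and 175 lower of 9735, so the balance of directions turned.

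**Figure D1:**
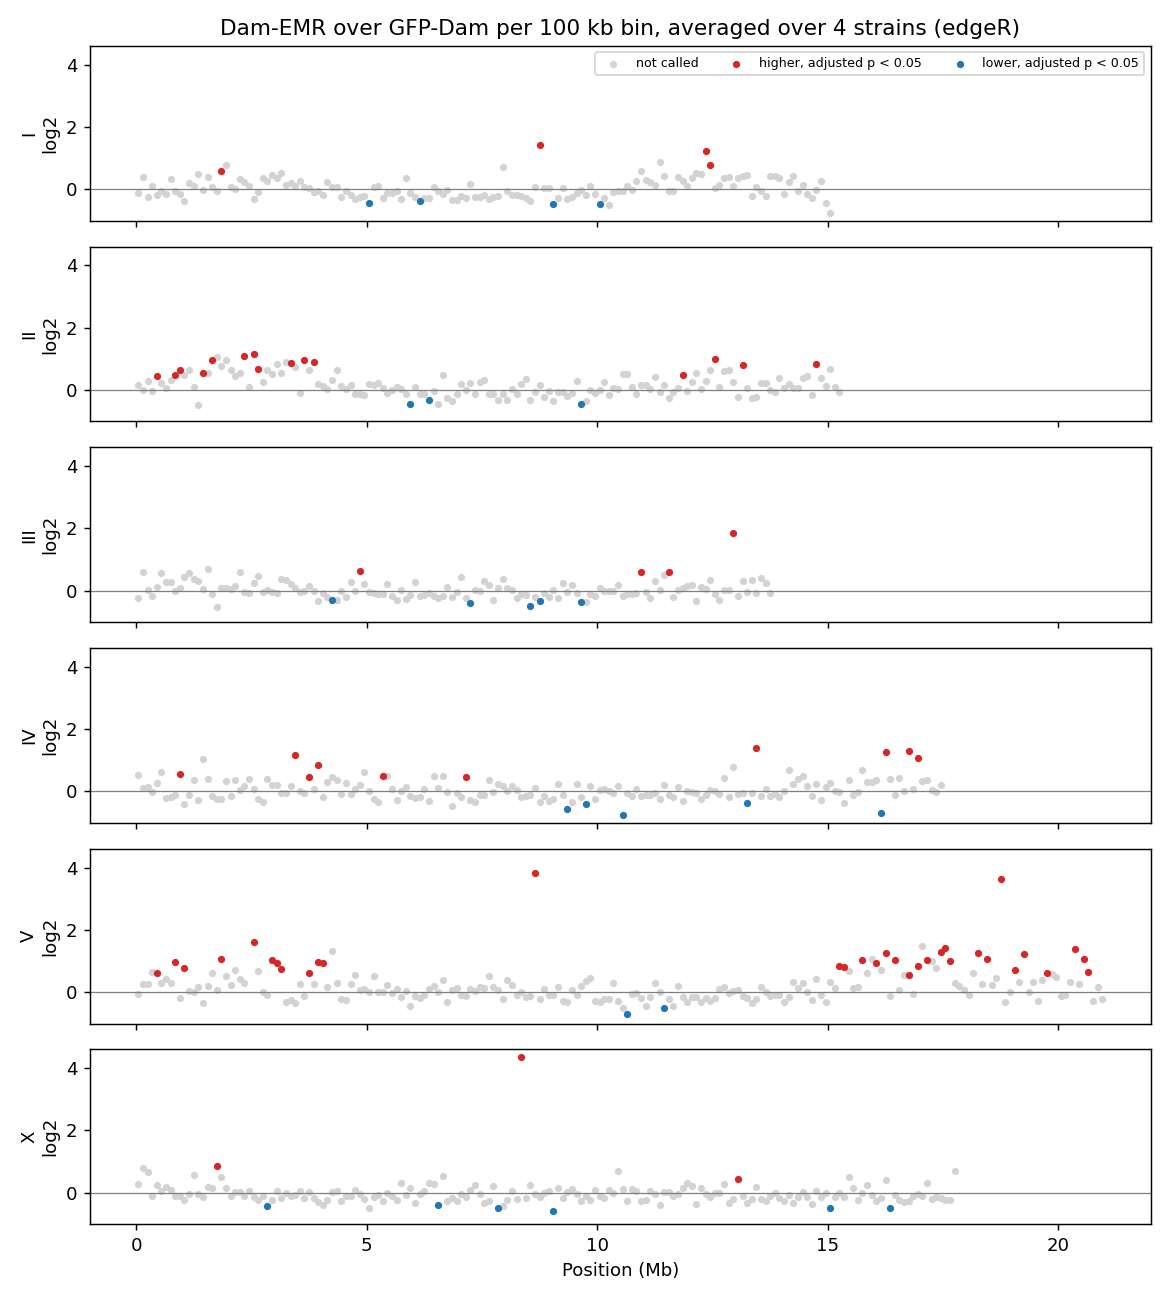
The log2 ratio of Dam-EMR to GFP-Dam reads (vertical axis) in each 100 kb bin along the 6 chromosomes (horizontal axis, Mb), averaged over the 4 strains by edgeR. Red and blue points are the 69 higher and 25 lower bins with adjusted p under 0.05, and grey points are the other bins; the red points gather on the arms of II, IV and V.

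In the autosomes as a whole, the mean log2 ratio of the arms minus that of the centre was 0.25 ± 0.23 (mean ± SD, n = 12 pairs) and above 0 in 11 of 12 pairs (exact two-sided sign-flip p = 0.00146). That test, and the others over 12 pairs, treat the pairs as independent. Pairs of the same round had correlated ratio profiles (median r over bins 0.355, against 0.0689 for the same strain), and flipping whole rounds cannot give an exact p under 0.25. Chromosome V showed the largest arm excess, 0.36 ± 0.35 (11 of 12 pairs, exact sign-flip adjusted p = 0.00586). By the same exact test II followed with 0.32 ± 0.38 (11 of 12, adjusted p = 0.00806). Chromosome I had 0.23 ± 0.18 (12 of 12, adjusted p = 0.00293) and IV with 0.18 ± 0.11 (11 of 12, adjusted p = 0.00293), with the exact test. Chromosome III had 0.11 ± 0.26 (7 of 12, exact adjusted p = 0.158) and X had −0.01 ± 0.09 (4 of 12, exact adjusted p = 0.58). Round means were 0.40, 0.17 and 0.17, so the excess was positive in each round. Both fusions on their own gave fewer reads per bin on arms than in centres, without a correction for GATC sites or mappability, with arm minus centre values at or under −0.68 log2 in every GFP-Dam library and from −0.07 to −0.87 in the Dam-EMR libraries. The arm excess is thus a smaller arm deficit in Dam-EMR than in GFP-Dam reads, in 11 of 12 pairs. Whether contact with emerin causes it was not tested.

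By zone, with each pair centred on its median bin, the right arm of V (0.33 ± 0.40, n = 12 pairs, 10 positive, exact sign-flip adjusted p over 18 zones = 0.0406) and the left arm of II (0.33 ± 0.41, 9 positive, adjusted p = 0.0406) were highest. By the same exact test came the left arm of V (0.21 ± 0.21, 11 positive, adjusted p = 0.00879) and the right arm of II (0.13 ± 0.17, 10 positive, adjusted p = 0.0337). The right arm of I had 0.10 ± 0.14, its left arm 0.03 ± 0.14, the arms of III 0.03 ± 0.16 (left) and 0.02 ± 0.08 (right), and the arms of IV 0.06 ± 0.16 (left) and 0.07 ± 0.15 (right), none past the threshold. The middle of I was negative in all 12 pairs (−0.16 ± 0.12, exact adjusted p = 0.00879) and the middle of IV in 10 of them (−0.11 ± 0.11, exact adjusted p = 0.0242). The right zone of X (−0.11 ± 0.12, exact adjusted p = 0.0246) and its left zone (−0.05 ± 0.05, exact adjusted p = 0.0205) were also low. The middles of II (−0.09 ± 0.15), III (−0.09 ± 0.20), V (−0.09 ± 0.14) and X (−0.07 ± 0.14) did not pass. Round 1 carried most of the signal on the II left and V right arms, with means of 0.73 and 0.66 against 0.03 and 0.05 in round 2 and 0.21 and 0.27 in round 3.

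**Figure D2:**
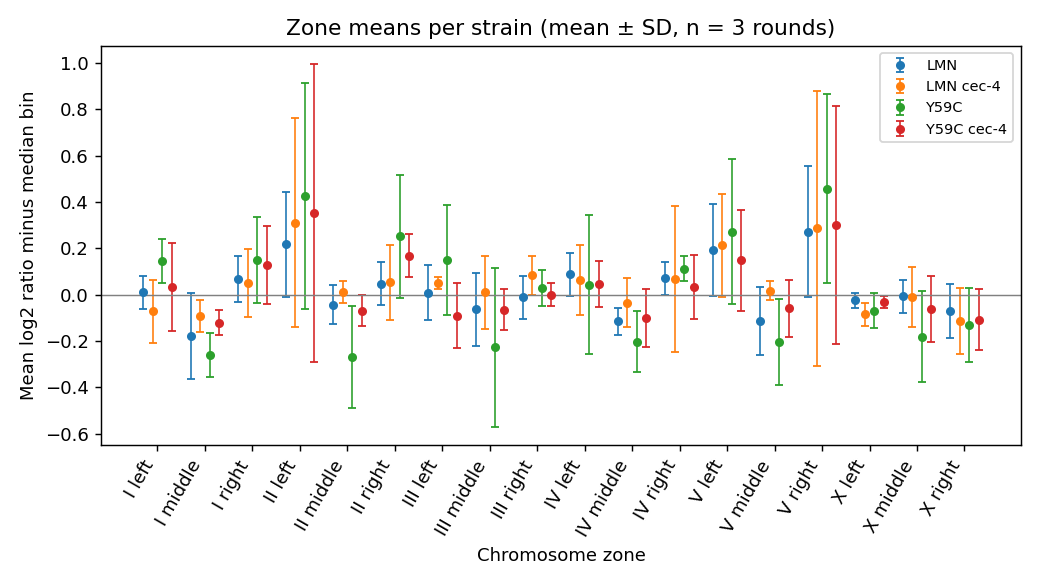
Mean log2 ratio of Dam-EMR to GFP-Dam, relative to the median bin of each pair, in 18 chromosome zones for the 4 strains. Points are means and bars are SD over 3 rounds; the left arm of II and both arms of V lie above 0 in each strain's mean, and the middle of I lies below 0.

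Gene families that crowd the arms had positive medians in the same averaged edgeR comparison, but no list passed limma's camera test, and for 3 of the families the median within pairs had the opposite sign. Means of the medians within pairs were −0.23 for chemoreceptor, −0.09 for F-box and −0.14 for nuclear hormone receptor genes. The 765 tested bins of chemoreceptor genes had a median log2 ratio 0.14 above that of all 10 kb bins, at the 98th percentile of random bin sets matched on chromosome and zone (98.05). Among them 24 bins were higher and 11 lower in edgeR when adjusted over the list alone, and 19 and 8 when adjusted over all bins. The bins of srh-141 (2.19) and the bin shared by sri-28, sri-29 and sri-30 (1.89) were positive in all 12 pairs. The bins of sru-48 (−1.19) and srt-32 (−2.43) were positive in none of the pairs. Medians of C-type lectin genes (0.32 above all bins, percentile 99.95), F-box genes (0.27, percentile 98.08), MATH-BATH genes (0.47, percentile 98.55) and nuclear hormone receptor genes (0.18, percentile 97.43) lay above those of most matched sets. In these families the bin of fbxa-163, bath-26, bath-33 and bath-47 (1.77) and the bin of srd-9 and nhr-216 (1.06) were higher in 12 of 12 pairs, and the clec-166, clec-167 and clec-168 bin (1.54) in 10. The calls adjusted over the list alone, higher and lower, were 3 and 2 for F-box, 2 and 0 for MATH-BATH, 6 and 3 for nuclear hormone receptor and 0 and 0 for C-type lectin bins. UDP-glucuronosyltransferase genes, by contrast, lay low (−0.30, percentile 0.87, 1 higher and 2 lower bins).

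Tissue lists were measured the same way. Body wall muscle genes, active in the tissue studied, had a median −0.24 relative to all bins (percentile 7.21), with 0 of 32 bins past the threshold over the list alone. Genes of other tissues had medians of 0.38 (neurons, percentile 99.42), 0.52 (germline, percentile 99.97), 0.18 (intestine, percentile 84.62), 0.08 (hypodermis, percentile 73.73) and 0.20 (pharyngeal muscle, percentile 75.33), and the yolk protein gene vit-2 was higher by 1.68 in 10 of 12 pairs. Genes of the nuclear envelope and its anchors had medians above the pair's median bin in 12 of 12 pairs (mean 0.39 ± 0.28, exact sign-flip p = 0.000488, the smallest that 12 pairs allow, adjusted p = 0.0103 over 21 lists). The 2 bins called in this list, lmn-1 (2.99) and emr-1 (1.42), are construct genes. Medians relative to all bins were −0.11 for housekeeping genes, −0.12 for developmental transcription factors, −0.29 for heat shock genes, −0.05 for ribosomal protein genes, 0.06 for cuticle collagens, 0.17 for cytochromes P450, −0.19 for insulin-like genes and 0.08 for histones. The collagen gene col-176 was lower in all 12 pairs (−0.99), rps-17 in 10 (−1.88), and the insulin-like list had 2 bins lower over the list alone. No list passed limma's camera test on the pair ratios (smallest adjusted p = 0.423, and adjusted p = 0.863 with an estimated correlation), and for housekeeping, heat shock, ribosomal protein and histone genes the camera direction was opposite to the sign of the median. For body wall muscle genes the mean of the medians within pairs was 0.05 (above the pair's median bin in 6 of 12 pairs).

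Within single strains, few 100 kb bins passed. In the Y59C strain Dam-EMR exceeded GFP-Dam on the right arm of II at npr-34, smg-9 and tac-1 (14700001 to 14800000, log2 1.30, SE 0.28, edgeR adjusted p = 0.0448). It also did on X at the monoamine transporter gene cat-1 (5700001 to 5800000, log2 1.24, SE 0.28, edgeR adjusted p = 0.0448). It fell short in the middle of V at ceh-22 (10600001 to 10700000, log2 −1.62, SE 0.33, edgeR adjusted p = 0.0409) and on X at kin-29 and vang-1 (2800001 to 2900000, log2 −1.07, SE 0.24, adjusted p = 0.0448). In the Y59C cec-4 strain the bin of nhr-89, nhr-169, clec-11, clec-12 and clec-17 on the right arm of I was higher (12400001 to 12500000, log2 1.66, SE 0.32, edgeR adjusted p = 0.026). Each of these 5 bins had the same sign in all 3 rounds. None kept its call when any round was left out, when only library totals were used, or with limma on the pair ratios (0 bins each). They are named here after their values were seen. In the Y59C strain limma with round as a block called 8 higher and 3 lower bins, and edgeR in 10 kb bins 6 higher and 87 lower of 9735. DESeq2 called 19 higher and 14 lower bins in the Y59C strain and 1 in the Y59C cec-4 strain. By zone, centred on the median bin, the middles of I (−0.26) and II (−0.27) were low in the Y59C strain (limma adjusted p = 0.0353 each). No zone passed before centring (smallest limma adjusted p in Y59C = 0.354) or in the other strains.

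No 100 kb bin passed in the GFP::LMN-1 strain or the GFP::LMN-1 cec-4 strain (edgeR, 0 of 1004 each), where 28 and 62 bins had an unadjusted p under 0.05, against 50.2 from 5% of the bins, and DESeq2 and limma on the pair ratios also called 0. limma voom with library weights called 0 and 40. At the level of gene lists in the GFP::LMN-1 strain, chemoreceptor genes had a median 0.24 above all bins and at the top of the matched sets (percentile 100), cuticle collagens 0.12 (percentile 97.85), ribosomal protein genes 0.15 (percentile 96.06) and UDP-glucuronosyltransferase genes −0.22 (percentile 4.93). None of the 21 lists passed limma's camera test (smallest adjusted p = 0.643, and 0.936 with an estimated correlation).

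The effect of the lamin substitution was asked by comparing the Dam-EMR to GFP-Dam ratio of the Y59C strain with that of the GFP::LMN-1 strain. The arm excess was 0.44 ± 0.35 in Y59C and 0.21 ± 0.20 in GFP::LMN-1 (n = 3 rounds each), a difference of 0.23 (exact two-sided permutation p = 0.5, where 3 against 3 rounds cannot go below 0.1). Round by round it was 0.72, −0.20 and 0.18, and without round 1 it was −0.01. In 10 kb bins it was 0.43 (SD 0.60) and with a pseudocount of 10 reads 0.33. Added reads weigh most in the round 3 Dam-EMR library of Y59C, with a median of 19 reads per 100 kb bin. They shrink its arm deficit (−0.77 log2) and so raise its arm excess. These 2 larger values therefore do not show a larger difference. The Y59C value itself was 0.24 without round 1 and 0.69 in 10 kb bins, and the GFP::LMN-1 value 0.10 without round 2. The largest zone differences, centred on the median bin, were −0.23 in the middle of II and 0.21 on its left arm, and no zone of 18 passed limma (0 had an unadjusted p under 0.05 before centring). With both cec-4 states combined, the arm excess was 0.15 higher with Y59C over 6 matched pairs (exact sign-flip p = 0.344, smallest possible 0.0313).

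Among single genes, the 10 kb bins that differed most between Y59C and GFP::LMN-1 were bins with many Dam-EMR reads in GFP::LMN-1 and none in Y59C. Among 8642 bins with at least 100 GFP-Dam reads in each strain, 286 held no Dam-EMR read in Y59C and 4 held none in GFP::LMN-1. The Y59C Dam-EMR libraries had more empty 10 kb bins in general, 22.7%, 20.9% and 42.2% in rounds 1, 2 and 3 against 10.9%, 7.71% and 5.30% in GFP::LMN-1, and the calls over the lists were all in the same direction, lower in Y59C. The bin of nhr-26 and ugt-50 on X (12690001 to 12700000) held 220 Dam-EMR reads over the GFP::LMN-1 libraries and 0 over the Y59C libraries, against 608 and 662 GFP-Dam reads (edgeR adjusted p = 0.00196 and 0.000515 adjusted over the list alone, 0.0482 over all bins). With the 0 set to 3 reads over the group, the change in log2 ratio was −5.57 or lower. The same held for bath-31 (II, 3731973 to 3733181, 400 reads against 0, −5.99 or lower), col-90 (III, 7948838 to 7950068, 187 against 0, −5.65 or lower), cyp-14A1 and cyp-14A2 (X, 146 against 0, −5.51 or lower). It also held for fbxb-70 (I, 84 against 0, −4.33 or lower), rpl-18 (IV, 72 against 0, −4.19 or lower), col-19 (X, 81 against 0, −4.07 or lower), ugt-62 (III, 66 against 0, −3.68 or lower) and cyp-32A1 (V, 47 against 0, −3.55 or lower). Of the genes with reads in both strains, rps-6 (I, 13952161 to 13953194) fell by 2.88 on the log2 scale (SE 0.77). The bin of rpl-23A.2 (I, 8329062 to 8329647) changed by −3.96 (SE 1.11) and cyp-34A7 (V, 3961681 to 3963815) by −5.20 (SE 1.49). The Hox gene php-3 held 1 read in Y59C, with an edgeR adjusted p over the list alone of 0.00984. All of these passed when adjusted over the list alone, and beyond the nhr-26 and ugt-50 bin none passed over all bins. The median 10 kb bin itself moved by −0.25 in this comparison. The bounds and the counts of bins without reads rest on reads summed over rounds, which weights rounds by depth. Most Dam-EMR reads were of round 3 in GFP::LMN-1 (3121281) and of round 2 in Y59C (2589969, against 35370 in round 3). These bounds and counts therefore cannot separate the strains from the rounds.

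Lists without a call in this comparison are given by their smallest p. They were unc-45 (log2 −5.27, SE 1.51, edgeR adjusted p over the list alone = 0.0514) for body wall muscle, tnt-4 (−1.60, SE 1.46) for pharyngeal muscle and cpr-1 (2.44, SE 1.20) for intestine. They were also rab-3 (−2.73, SE 1.31) for neurons, mex-6 (SE 1.82, edgeR adjusted p = 0.214) for germline. For other lists they were tbp-1 (−2.83, SE 1.26) for housekeeping, hsp-16.2 (2.41, SE 1.13) for heat shock and set-25, a histone H3 lysine 9 methyltransferase gene, (3.74, SE 1.29) for the nuclear envelope and anchor list. For chemoreceptors it was srx-67 (1 Dam-EMR read in Y59C against 85), for C-type lectins clec-100 (1 against 240), for insulin-like genes ins-1 (0 against 56) and for histones his-10 (0 against 33). The calls per list, adjusted over the list alone, were 3 bins of ribosomal protein genes, 3 of cytochromes P450, 2 of UDP-glucuronosyltransferases and 1 each of hypodermis, developmental transcription factors, F-box, nuclear hormone receptors, MATH-BATH and cuticle collagens, all of them lower. Relative to all bins the MATH-BATH median was 1.00 and the UDP-glucuronosyltransferase median −0.55, and no list passed camera (smallest adjusted p = 0.295, with an estimated correlation adjusted p = 0.95).

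No 100 kb bin differed between Y59C and GFP::LMN-1 (edgeR 0 of 1004, 37 with unadjusted p under 0.05, smallest adjusted p = 0.997), and DESeq2, limma on the pair ratios and voom also called 0. In 10 kb bins edgeR called 0 higher and 2 lower of 9735. In 100 kb bins of the GFP-Dam libraries alone 0 differed (0 with unadjusted p under 0.05), and in Dam-EMR libraries alone 0 (93 with unadjusted p under 0.05), with 0 by DESeq2 in both. In 10 kb bins of the Dam-EMR libraries alone edgeR called 9 higher and 109 lower (1775 with unadjusted p under 0.05). In those of the GFP-Dam libraries alone it called 0, and 1 bin had an unadjusted p under 0.05. Both used 1 spread estimate over all libraries. The median dispersion was 0.072 over these libraries and 0.0231 over the GFP-Dam libraries. Such tests are likely too strict for GFP-Dam and too lenient for Dam-EMR, so their counts do not show which fusion changed. The lamin effect averaged over the cec-4 states gave 0 bins (32 with unadjusted p under 0.05, smallest edgeR adjusted p = 0.911, 0 by DESeq2). Simulated 4-fold changes in this comparison were found in 86% of 50 bins and 2-fold changes in 20%.

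Loss of cec-4 was asked first with wild-type lamin. The arm excess was 0.14 ± 0.21 in the GFP::LMN-1 cec-4 strain and 0.21 ± 0.20 in GFP::LMN-1 (n = 3 each), a difference of −0.08 (exact permutation p = 0.8). By round the difference was 0.18, −0.53 and 0.12, and without round 2 it turned to 0.15. The GFP::LMN-1 cec-4 value was 0.04 without round 1 and 0.25 without round 2, and the GFP::LMN-1 value was 0.10 without round 2. The middle of V (0.13), the right arm of III (0.09) and the left arm of II (0.09) had the largest positive centred zone differences. The left arm of I (−0.08) had the most negative one, and none of 18 zones passed limma (0 with unadjusted p under 0.05). No 100 kb bin differed (edgeR 0, 10 with unadjusted p under 0.05, and 0 by DESeq2, limma and voom).

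Whether cec-4 loss changes emerin contacts in the presence of Y59C was asked by comparing the Y59C cec-4 strain with the Y59C strain. The arm excess was 0.20 ± 0.10 and 0.44 ± 0.35 (n = 3 each), a difference of −0.24 that was negative in each round (−0.55, −0.13 and −0.04; exact permutation p = 0.4; exact sign-flip p over rounds = 0.25, the smallest that 3 rounds allow). Without round 1 it was −0.09, and in 10 kb bins −0.49 (SD 0.19). The 10 kb value has the limit given above for reads added to the shallow Y59C library of round 3. The centred zone difference was −0.24 on the left arm of III and 0.20 in the middle of II, with 0 of 18 zones past limma's threshold or an unadjusted p under 0.05. The cec-4 effect over both lamins was −0.16 over 6 matched pairs (exact sign-flip p = 0.344).

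Hypodermis genes formed the only list that passed in this comparison, and it did so with the preset correlation only. The list lay lower in Y59C cec-4 (limma camera adjusted p = 0.0438, adjusted p = 0.238 with an estimated correlation, adjusted p = 0.0566 with round as a block). Its median was −0.45 relative to all bins, at percentile 11.23 of the matched random sets, so it was not extreme among them. Its 3 bins called when adjusted over the list alone went both ways. The cuticle collagen genes dpy-7 (X, 7536467 to 7537792, log2 −3.63, SE 0.95, edgeR adjusted p over the list alone = 0.00465) and sqt-3 (V, 12352745 to 12354320, log2 −6.09, SE 1.80, adjusted p = 0.01) were lower. The adult collagen gene col-19 held 301 Dam-EMR reads against 0 in Y59C (5.73 or higher). Of the 286 bins that held no Dam-EMR read in Y59C (among 8642 with at least 100 GFP-Dam reads in each strain), 281 held reads in Y59C cec-4. That is 98.3%, against 99.6% of all such bins, so reads at these genes do not set them apart from other bins. Both comparisons share the Y59C libraries, and the list calls include nhr-26 (192 against 0, 4.61 or higher), bath-31 (249 against 0, 4.80 or higher), fbxb-70 (167 against 0, 4.82 or higher). They also include ugt-62 (409 against 0, 5.77 or higher), the ugt-15, ugt-16 and ugt-18 bin (181 against 0, 5.49 or higher), and the col-50 and col-51 bin (98 against 0, 4.42 or higher). Genes with reads in both strains were fbxc-14 and fbxc-17 (II, 970001 to 980000, log2 5.47, SE 1.12, edgeR adjusted p over the list alone = 0.00409) and cyp-33E1 (IV, 8645521 to 8648429, log2 4.84, SE 1.17, adjusted p = 0.0154), and php-3 held 216 reads against 1. Lower bins held fbxb-31 (0 reads against 143, −7.73 or lower) and col-86 (0 against 26, −4.57 or lower). None of these passed over all bins, where the median 10 kb bin moved by 0.26. The bounds again rest on reads summed over rounds of unequal depth. Round 3 gave 3117031 Dam-EMR reads in Y59C cec-4 and 35370 in Y59C, so strain and round are not separated.

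For the lists without a call, the smallest p belonged to unc-45 (log2 4.44) in body wall muscle, tnt-4 (3.19, SE 1.49) in pharyngeal muscle and ifc-2 (−2.50, SE 0.91) in intestine. It belonged to mec-3 (0 Dam-EMR reads against 21) in neurons, mex-6 (−4.29, SE 1.80) in germline, tbp-1 (3.10, SE 1.28) in housekeeping genes. Among the other lists it was hsp-16.2 (−1.84, SE 1.13) in heat shock, npp-3 (2.53, SE 1.01) in the nuclear envelope list, srg-53 (0 against 272 reads) in chemoreceptors. The last were clec-24 (524 against 2) in C-type lectins, rpl-22 (1.94, SE 0.62) in ribosomal proteins, ins-28 (4.28, SE 1.63) in insulin-like genes and his-55 (−2.06, SE 1.16) in histones. At 100 kb, 0 bins differed (edgeR, 50 with unadjusted p under 0.05, smallest adjusted p = 0.801, and 0 by DESeq2, limma on the pair ratios and voom). In 100 kb bins of the Dam-EMR libraries alone edgeR called 0 (114 with unadjusted p under 0.05), DESeq2 2 higher and voom 1, while 10 kb bins gave 269 higher and 101 lower. In GFP-Dam libraries alone all 3 called 0 (1 with unadjusted p under 0.05), and edgeR also called 0 in 10 kb bins. The shared spread estimate limits these single-fusion counts in the same way, so they do not show which fusion changed. The cec-4 effect averaged over lamins gave 0 bins (26 with unadjusted p under 0.05, edgeR adjusted p = 0.992 at the smallest, 0 by DESeq2).

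The Y59C cec-4 strain was also compared with GFP::LMN-1, to ask whether the double mutant combination differs from the wild-type lamin. The arm excess was 0.20 and 0.21, a difference of −0.01 (exact permutation p = 1), which was 0.17, −0.33 and 0.14 by round and 0.15 without round 2. The left arm of II (0.13), the right arm of II (0.12) and the left arm of III (−0.10) had the largest centred zone differences, with 0 of 18 zones past limma's threshold. Developmental transcription factors had a median 0.68 above all bins (percentile 98.08) and ribosomal protein genes −0.27 (percentile 1.78), with no list past limma's camera test (smallest adjusted p = 0.487, and 0.916 with an estimated correlation). Over the list alone, 1 F-box bin and 1 cuticle collagen bin differed, and no list bin did over all bins. No 100 kb bin differed (edgeR 0, 17 with unadjusted p under 0.05, 0 by DESeq2, limma and voom).

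The test of the difference between the cec-4 effects in the Y59C and wild-type backgrounds gave an arm excess of −0.17 (exact sign-flip p over 3 rounds = 0.75) and turned to 0.12 without round 1. The left arm of III had a centred zone interaction of −0.28 and the right arm of V −0.17, and 0 of 18 zones passed limma. At 100 kb no bin passed (edgeR 0, 24 with unadjusted p under 0.05, smallest adjusted p = 0.562, 0 by DESeq2, limma and voom). In the authors' deposited table of log2 ratios, averaged over rounds, the arm excess was 0.22 in GFP::LMN-1, 0.18 in GFP::LMN-1 cec-4, 0.45 in Y59C and 0.22 in Y59C cec-4.

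**Figure D3:**
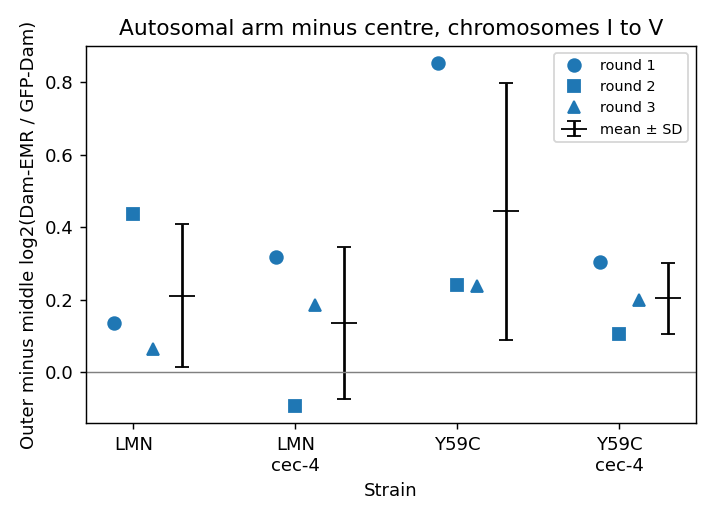
Mean log2 ratio of Dam-EMR to GFP-Dam on the arms minus the centres of chromosomes I to V (vertical axis, log2) for each of the 12 pairs, by strain and round. The horizontal bars and error bars are the mean and SD of 3 rounds; 11 of 12 points lie above 0, and the highest is round 1 of the Y59C strain at 0.85.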

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

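The tests of explanations in this part were all chosen after the results they address had been seen. Mitochondrial DNA, which lay outside the comparisons, gave more reads in Dam-EMR than in GFP-Dam libraries. The highest Dam-EMR library, the GFP::LMN-1 cec-4 strain in round 1, had a mitochondrial level of 83.3 CPM, the highest GFP-Dam library had 5.13, and 7 Dam-EMR libraries lay above that. The Dam-EMR library was the higher one in 8 of 12 pairs, with 299 reads in all against 55. No explanation was tested.

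The Dam-EMR to GFP-Dam profiles of round 1 spread more widely over bins than those of other rounds in 3 of 4 strains. In the GFP::LMN-1 strain they did not (SD 0.48 in round 1, 0.61 in round 2 and 0.46 in round 3). Counting noise of independent reads is argued against as the whole of the spread, since the observed spread was at least 3.21 times the simulated counting spread in all 4 round 1 pairs. The median of this ratio was 4.93 in round 1, against 10.1 and 6.60 in rounds 2 and 3. It therefore cannot tell why round 1 spread more widely, and reads copied from few molecules were not simulated. Loss of starting molecules independently in each library stays open. The 4 strains shared their round 1 profile with correlations over bins of no less than 0.289 (median 0.413, against 0.238 and 0.305 in rounds 2 and 3). The lowest values in rounds 2 and 3 were 0.132 and 0.215. The GFP-Dam libraries in these ratios themselves correlated within a round (r from 0.446 to 0.843). The correlations therefore cannot tell whether independent loss widened the round 1 profiles. A shared property of the round 1 preparations stays open, and no biological explanation was tested for it.

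The larger arm excess in Y59C than in GFP::LMN-1 may go with the round 1 libraries, since without them the difference was −0.010. The lamin mutation itself stays open as a cause, because the lamin effect over 6 matched pairs had an exact sign-flip p of 0.344.

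A pair of single bins held many Dam-EMR reads in round 1, the X bin of drd-5 and npr-28 (1.13% to 4.26% of each library) and the V bin that holds asp-13 and ZC190.4 (4.35% to 22.7%). Contact over a broad domain is argued against for the X bin, because the median of its 10 flanking bins was −0.89. Construct or plasmid DNA in the round 1 preparations could be a source and stays open. The mean ratio of 3 construct genes, lmn-1, emr-1 and hsp-16.41, lay at percentile 99.96 of random sets of bins in round 1, at 99.68 in round 2 and at 83.24 in round 3. Emerin contact at those genes would give the same value. The tagged lamin and the hsp-16.41 promoter were in the strains of both fusions, so their construct copies alone would not raise the ratio. Of the 3 genes only emr-1 was particular to the Dam-EMR constructs. Its mean centred log2 ratio in round 1 was 2.37, against 3.74 for lmn-1 and 3.33 for hsp-16.41. The libraries behind these means differed. For lmn-1 the round 1 ratio was 5.98 in GFP::LMN-1 cec-4, 5.59 in Y59C, 2.76 in GFP::LMN-1 and 0.64 in Y59C cec-4. For emr-1 they were 4.29, 3.80, 0.00 and 1.40 in the same order. The baf-1 bin, not among the 3 genes, had 5.02 in the GFP::LMN-1 cec-4 pair. The values at these genes do not test the X and V bins themselves. Excess in single bins was not limited to Dam-EMR or round 1. The III bin of bus-22 and bath-41 held 20.9% of the round 3 GFP-Dam library of Y59C cec-4. It held 11.2% of the round 3 Dam-EMR library of GFP::LMN-1 cec-4 and 0.142% to 1.32% of the others. The ribosomal DNA bin on I held 24.2% to 30.0% of each round 3 GFP-Dam library. The round 3 Y59C cec-4 pair had a median log2 ratio of 0.71. Its GFP-Dam library held 20.9% of reads in the III bin and 30.0% in the ribosomal DNA bin. Its Dam-EMR library held 0.27% and 15.5% there. Scaling to library totals therefore raises the ratio of the other bins in this pair, before centring. Causes of the excess in single bins were not tested.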

How the results depend on the processing

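All alternatives for the averaged results, and voom, reads summed over rounds, leaving out bins with excess or ribosomal DNA reads, leaving out the shallowest pair and centred zone ratios were chosen after the data were seen. Of the alternatives 352 were counted as unchanged. For counts of calls this compares the size of the count, not which bins were called. Many of these counts had no call under either setting. The averaged association without round 1 was counted as unchanged with 79 calls against 94, although only 18 higher and 14 lower bins were shared. An arm value of a single strain was unchanged within 1 SD, which for 3 rounds allows changes of over 1.5 times. Arm differences between strains and the interaction were counted as unchanged whenever the sign was kept, whatever the size. The Y59C cec-4 against Y59C difference, −0.24, was thus unchanged from −0.49 to −0.09. Of the rest 15 weakened a result, 7 strengthened it, 13 moved it and 7 reversed it; the cause was not tested. The alternative that placed genes by their 5' end was not run, because the annotation used gives no strand.

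With library totals only, the calls were 0 in Y59C, 0 in Y59C cec-4 and 43 averaged over strains, against 4, 1 and 94. With DESeq2 they were 33 in Y59C, 157 averaged and 2 in Dam-EMR alone for Y59C cec-4 against Y59C. With limma on pair ratios they were 0 in Y59C, 0 in Y59C cec-4 and 3 averaged, and with round as a block in limma 11 in Y59C and 5 in Y59C cec-4; in edgeR the block gave 5, 1 and 106, and changed no other call apart from the hypodermis list. With only the groups compared both strains had 0. With voom the counts were 40 in GFP::LMN-1 cec-4, 1 in Y59C, 3 in Y59C cec-4 and 1 in Dam-EMR alone for Y59C cec-4 against Y59C.

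In 10 kb bins the called share was 0.955% in Y59C (6 higher and 87 lower, against 2 and 2), 0 in Y59C cec-4, 0.0205% for Y59C against GFP::LMN-1, 1.21% in Dam-EMR alone for the same comparison, 3.80% in Dam-EMR alone for Y59C cec-4 against Y59C, 3.09% averaged (126 higher and 175 lower, against 69 and 25) and 0.0616% for the averaged lamin effect. The hypodermis call ended, leaving 0 lists, with the estimated correlation and also with round as a block (adjusted p = 0.0566).

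Leaving out a replicate gave 0 to 0 calls in Y59C and in Y59C cec-4, and 1 to 79 averaged. With a replicate left out, arm differences ranged from −0.010 to 0.45 for Y59C against GFP::LMN-1, from −0.20 to 0.15 for GFP::LMN-1 cec-4 against GFP::LMN-1, from −0.34 to −0.09 for Y59C cec-4 against Y59C, from −0.10 to 0.15 for Y59C cec-4 against GFP::LMN-1, and from −0.45 to 0.12 for the interaction. The Y59C cec-4 against GFP::LMN-1 difference, −0.01, was 0.0049 with 25% arms, 0.014 with the median over bins and 0.0030 from the deposited log2 values. With reads summed over rounds the arm excess was 0.12 in GFP::LMN-1, 0.075 in GFP::LMN-1 cec-4, 0.39 in Y59C and 0.026 in Y59C cec-4, and the Y59C cec-4 against Y59C difference was −0.36. Over all 13 alternatives that difference ran from −0.49 to −0.09. A median of 11.7% of 10 kb bins held no read in a Dam-EMR library. In the shallowest library 35% would be empty from counting alone, where 42.2% were, and in the round 2 library of GFP::LMN-1 cec-4 0.57%, where 21.2% were.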

Other observations

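All tests by regrouping the samples in this part had their predictions written after the results were seen. For the averaged association, 1 of 100 splits gave as many bins as the real 94, the real split itself, and the highest other gave 5, where the splits swapped the fusions within pairs. They treat the pairs of a round as independent, although these shared profiles, and the 3 rounds swapped whole are too few for a share under 0.05. Without round 3 the count was 1. For the Y59C association the real split gave 4 and the highest other 0, and for Y59C cec-4 1 and 0 (1 of 10 splits each), but 10 splits are too few for a share under 0.05.

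Among differences, all 10 of 10 splits reached the real 0 for Y59C against GFP::LMN-1, GFP::LMN-1 cec-4 against GFP::LMN-1, Y59C cec-4 against GFP::LMN-1, the associations of both wild-type lamin strains, both GFP-Dam comparisons and the zone tests, with 0 as the highest other. For Y59C cec-4 against Y59C the highest other split called 36 bins, in Dam-EMR libraries alone 215, and for Y59C against GFP::LMN-1 in Dam-EMR alone 5. Counts of 36 and 215 beside a real 0 point to a structure of the samples, and what those splits share was not tested. The interaction and averaged effects reached the real 0 in 100 of 100 splits, with highest other counts of 74 (interaction), 3 (zone interaction), 114 (lamin) and more than 100 (cec-4). For lists, 3 of 10 splits reached the real 1 in Y59C cec-4 against Y59C (highest other 4). It was 10 of 10 for the real 0 in the other differences (highest 0 and 4), and 4 of 4 for the real 0 in GFP::LMN-1 (highest 0). Where the real count was 0, every split reached it by construction, so those splits test nothing.

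Ratio profiles of the same strain from different rounds had a median r over bins of 0.0689, and those of different strains from the same round 0.355, while pairs sharing neither had 0.107.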
